A study of Caldicellulosiruptor saccharolyticus with 4 samples.

How the data were processed

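Total RNA of Caldicellulosiruptor saccharolyticus grown on rhamnose, glucose, xylose or a 1:1 mixture of glucose and xylose was turned into amino-allyl cDNA and labelled with Cy3 in channel 1 or Cy5 in channel 2, per the labels. The authors deposited 1 scanner table for each of the 4 arrays, with the mean intensity of each spot and of its local background in each channel, not normalized, per the file headers. The tables also hold a signal-to-noise score for each spot, which the authors deposited without a definition and which was not used here. The scanner and its software are not given in the sources used here. The authors also deposited a table of log2 values for 2679 loci, with no method stated. Its 4 columns close exactly over the loop (largest error 1e-09), so they are differences fitted over all arrays and not values of single arrays. Their column medians were -0.02, -0.01, -0.06 and -0.15.

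That table was set against several versions of the loop fit, and the closest found was the one with local background subtracted and median centring, chosen after these comparisons were seen. Across loci, r was 0.988, 0.982, 0.976 and 0.989, with slopes of 0.993, 0.980, 0.905 and 0.980, for glucose minus rhamnose, glucose minus xylose, mixture minus xylose and mixture minus rhamnose. The scale was therefore taken as log2 and the columns as these differences; the authors' normalization and centring stay unknown.

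Intensities were background-corrected with limma's normexp method and an offset of 50, and normalized within each array with 1 loess curve, in which empty spots had weight 0. The 5 spots of a probe were averaged. The log2 ratio of channel 2 over channel 1 was fitted with lmFit for 3 differences between substrates, which leaves 1 residual degree of freedom for each probe, and moderated with eBayes (prior degrees of freedom 57.9, prior SD 0.77). A dye effect that is constant for a probe cancels in the differences of a closed loop and adds to the residual. All 6 comparisons among the substrates were tested over 2793 probes at a Benjamini-Hochberg adjusted p under 0.05. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9 were used.

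A probe counted as above background in a channel when its mean signal net of local background passed the 95th percentile of the empty spots. Where a probe was below it in both channels of a substrate, a lower bound of the fold was taken from channel values after loess and Aquantile normalization: the bright substrate's mean against the mean, for each dim channel, of the higher of the lowest signal among probes above background and the probe's own. Such bounds are open to dye bias and are not on the scale of the fitted values. They leave out the spread between hybridisations, so they are estimates and the fold can lie below them. Of 6 bounds, 3 were over the fitted fold or the smallest fold with an array left out and are not given, a rule chosen after the values were seen. Each of the 6 was over the fold of at least 1 alternative, so those given are estimates under the reported normalization only.

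The design, tests, alternatives and the rule for named loci were fixed before the data were examined. The rule took, in each comparison and direction, the probes past the threshold whose 2 independent paths around the loop had the same sign, ranked by log2 difference. It allowed 6 in each direction, and this was lowered to 2 because the files pair no names with the IDs. The planned tests of gene lists by product name, with their alternatives, were not run for the same reason. In addition, 1 probe ID that is not a locus number is not printed.

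The fit was tested on simulated loops with the spread of the real probes, for glucose against rhamnose over 2793 probes. It recovered 29.9% of 67 probes with a true log2 difference of 2, 100% of 67 with one of 4 and 100% of 66 with one of 5, and it called 0 unchanged probes. The simulated noise was normal and independent between arrays. The real spread also holds dye effects that cancel in the differences, so these rates need not hold for the real arrays.

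Alternatives to the background correction, normalization, averaging of spots, filter on dim probes, moderation, label of the array of the mixture and rhamnose, and arrays used were run. The separate-channel fit with a dye term gave an estimated correlation between channels of 1, with which it could not be fitted, so 0.21 from the design without that term was used. In the fit that kept the replicate spots, the dye term left no spread between arrays to estimate and the array correlation was 0, so its p-values measure the spread between spots of 1 array. Subtraction of the empty spots' median (floor 16), subtraction of the local background with loess or with median centring, the separate-channel fit without a dye term, the position of the mixture without each array and the channel-level checks were chosen after seeing the data.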

Results

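Caldicellulosiruptor saccharolyticus is an extremely thermophilic bacterium that ferments plant sugars. Per the labels, it was grown at 70 °C and pH 7 on 4 g per litre of L-rhamnose, glucose, xylose or a 1:1 mixture of glucose and xylose, after 3 subcultures on the same substrate. RNA from growth on the 4 substrates was compared on 4 2-colour arrays that form a closed loop: rhamnose with glucose, glucose with xylose, xylose with the mixture, and the mixture with rhamnose. Each substrate was hybridised on 2 arrays, once with each dye, and there was 1 array for each pair. The labels do not say whether the 2 hybridisations of a substrate came from separate cultures, so the spread behind the p-values may be technical. That spread is estimated from the sum of the 4 ratios around the loop, so it also holds the dye effect of a probe. Print blocks held 67.4% of the variance of the mean of the 4 ratios. The median SE on glucose against rhamnose was 0.66, and 0.27 with a loess curve per print block. Each array held 15552 spots, of which 1587 were empty, and 2793 probes were spotted 5 times each. The median probe signal over the median of the empty spots lay between 1.27 for Cy5-labelled rhamnose on the array with the mixture and 4.68 for Cy3-labelled glucose on the array with xylose. The share of probes above the 95th percentile of the empty spots ranged from 66.4% to 90.8% over the 8 channels. The number of arrays limits the precision.

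The files do not pair the locus IDs with gene names or products, so at most 2 IDs that rose and 2 that fell are given for each comparison, without a function. All log2 values are fitted differences over the 4 arrays with their standard error (SE), and adjusted p is that of limma's moderated test with Benjamini-Hochberg adjustment over 2793 probes. The direction of the ratios is likely rather than settled: the scanner tables number the channels without naming the dyes, and channel 1 was taken as the Cy3 channel of the labels. In this direction 24 probes were above the empty spots in both channels or in neither for each substrate, with at least 1 substrate of either kind, against 5 probes with the channels exchanged. Probes above in both channels of 1 substrate and in neither of another numbered 139 against 127.

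The first comparison asked which transcripts differed between growth on glucose and on rhamnose, the substrate that the design text expected to take another route into central metabolism. Of 2793 probes, 24 differed, 7 higher and 17 lower on glucose. Csac_1628 rose on glucose by a log2 difference of 4.83 ± 0.66 (SE, 4 arrays, limma adjusted p = 1.03e-06). Csac_0622 rose by 3.82 ± 0.66 (limma adjusted p = 9.44e-05). Csac_0872 had a log2 difference of -5.22 ± 0.68 and Csac_0866 one of -5.18 ± 0.72 (limma adjusted p = 4.92e-07 and 1.20e-06). In the dim substrate each of these 4 loci was above the empty spots in 1 of 2 channels, so the order of their differences is not measured. Without the array of these 2 substrates the values were -3.05 for Csac_0872 and -9.06 for Csac_0866. Without any 1 of the other 3, Csac_0866 stood at -3.88, each time the ratio of the direct array alone. With an array left out the loop is open and the dye effect of a probe no longer cancels. Such values, here and below, may therefore differ through dye bias alone. Csac_0872 and Csac_0866 lie in a stretch of 12 consecutively numbered loci that all were at least 2-fold lower on glucose, 10 of which passed the test. With a loess curve per print block instead of 1 curve per array, 77 probes differed, 34 higher and 43 lower, and 21 were called in the same direction by both normalizations. With median centring the split was 1 higher and 6 lower.

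On xylose, 18 probes differed from rhamnose, 9 in each direction. Csac_0240, above the empty spots in 1 of 2 rhamnose channels, rose by a log2 difference of 5.88 ± 0.76 (SE, 4 arrays, limma adjusted p = 4.16e-07). Csac_0242 was not above the empty spots in either rhamnose channel and was higher on xylose (limma adjusted p = 7.86e-07). Its fold was estimated as at least 19.5. The unadjusted 95% interval of its fitted log2 difference, 4.07 to 7.13, reached below that bound. Csac_0240 and Csac_0242 lie in a stretch of 4 consecutively numbered loci, all 4 of which rose. The 2 loci named as lower on glucose were lower on xylose too: Csac_0866 had a log2 difference of -6.07 ± 0.83 and Csac_0872 one of -4.88 ± 0.78 (limma adjusted p = 7.86e-07 and 2.41e-05). Without single arrays they ranged from -3.48 to -8.66 for Csac_0866 and from -3.44 to -6.33 for Csac_0872. Normalization by print block gave 43 probes, 21 higher and 22 lower, of which 14 were called in the same direction by both. With median centring the split was 4 higher and 2 lower.

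On the mixture of glucose and xylose, 14 probes differed from rhamnose, 8 higher and 6 lower. Csac_0692 rose by a log2 difference of 5.13 ± 0.66 (SE, 4 arrays, limma adjusted p = 3.43e-07). Csac_0242 was higher on the mixture (limma adjusted p = 6.62e-07), and its fitted value of 4.80 became 5.89 without the array of these 2 substrates. Its fold was estimated as at least 20.0. The unadjusted 95% interval of the fitted log2 difference, 3.48 to 6.13, reached below that bound. Csac_0866 had a log2 difference of -5.43 ± 0.72 and Csac_0865 one of -5.13 ± 0.69 (limma adjusted p = 4.48e-07 and 5.29e-07). Csac_0866 was above the empty spots in 1 of 2 channels of the mixture. Without the array of the mixture and rhamnose, the values of the loci that fell were -1.55 for Csac_0866 and -2.21 for Csac_0865. Normalization by print block gave 27 probes, 14 higher and 13 lower, of which 12 were called in the same direction by both.

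**Figure D1:**
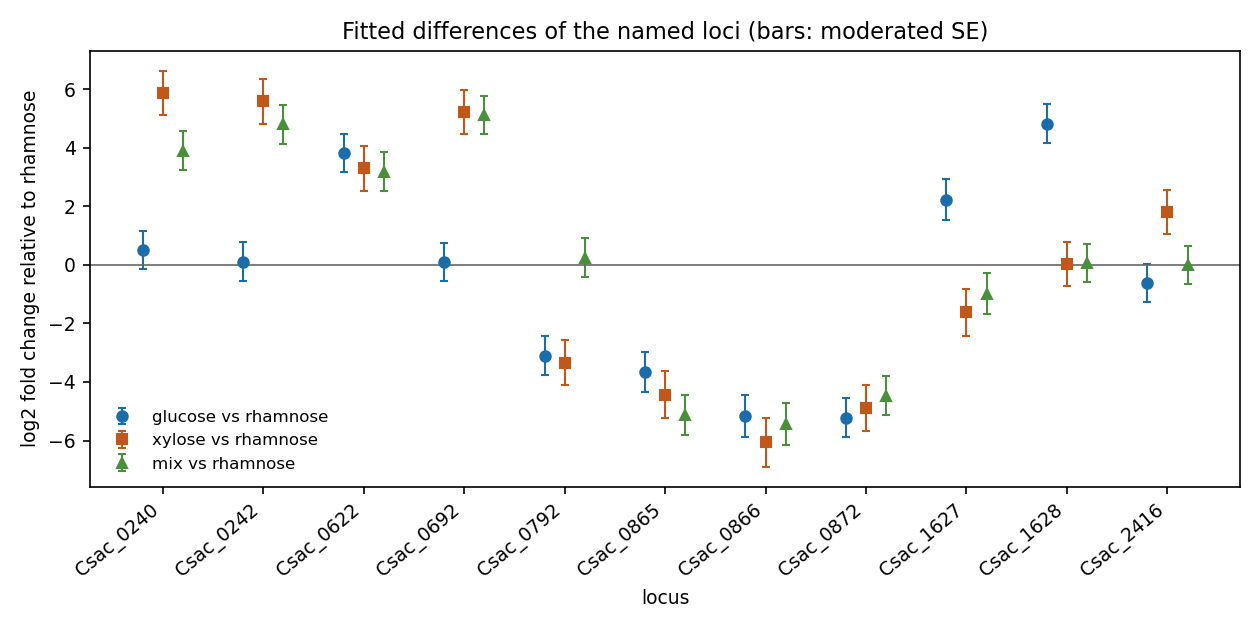
Fitted log2 difference from rhamnose (y axis) of the 11 loci named in the text (x axis), for glucose (circles), xylose (squares) and the mixture (triangles), with bars for the moderated standard error. Csac_0866 and Csac_0872 lay below 0 on all 3 substrates, while Csac_0242 lay at 5.60 on xylose and 4.80 on the mixture; loci whose dim channel was not above the empty spots are drawn at the fitted value, which is no bound.

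Calls against rhamnose overlapped to different degrees between the substrates. Of 17 probes lower on glucose and 9 lower on xylose, 8 were the same, where independent lists would share 0.0548. All 6 probes lower on the mixture were also lower on glucose, against 0.0365 for independent lists. Of the 9 probes higher on xylose and the 8 higher on the mixture, 6 were the same, against 0.0258. Lower on both xylose and the mixture were 5, against 0.0193. Among higher probes, glucose shared 1 of its 7 with xylose and 3 with the mixture, against 0.0226 and 0.0201. In 100 simulated loops with the called effects placed on unrelated probes and the rhamnose hybridisations shared, the mean overlap was at most 0.08 in any of the 6 pairings and none was over 1. Unchanged loops shared 0 on average, which says little, since a loop without effects gives few calls. The simulations assume the fitted spread, so part of the overlap may still come from the shared rhamnose channels. The stretch of 12 loci of Csac_0866 and Csac_0872 held 10 of the probes called on glucose, 6 on xylose and 5 on the mixture. The stretch of Csac_0240 held 4 on xylose and 3 on the mixture, and that of Csac_0692 held 3 and 2. Independent lists and simulations treat such neighbours as unrelated, so the overlaps rest on fewer independent units than the counts. Over all 3 substrates, 5 probes were lower and 1 was higher in every comparison with rhamnose.

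Xylose and glucose were compared directly on 1 array and through the other 3. There were 14 probes called, 8 higher and 6 lower on xylose, and all 14 were also called with print-block normalization, which gave 23. Csac_0242 was not above the empty spots in either glucose channel and was higher on xylose (limma adjusted p = 3.89e-08), with a fitted log2 difference of 5.48 that was 4.40 without the array of these 2 sugars, and no bound of the fold is given. Csac_0240 rose by a log2 difference of 5.38 ± 0.66 (SE, 4 arrays, limma adjusted p = 3.89e-08). Csac_1628, above the empty spots in 1 of 2 xylose channels, had a log2 difference of -4.80 ± 0.66 (limma adjusted p = 4.93e-07). Csac_1627 was lower on xylose, where it was not above the empty spots (limma adjusted p = 0.000365), at -3.85 over all 4 arrays. Its value was -0.79 without the array of these 2 sugars and -4.87 without any 1 of the other 3. The latter is each time the ratio of the direct array alone. A dye effect alone can set such values apart.

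The mixture differed from glucose at 7 probes, 6 higher and 1 lower. Csac_0692 rose by a log2 difference of 5.03 ± 0.76 (SE, 4 arrays, limma adjusted p = 3.27e-05). Csac_0242 was higher on the mixture (limma adjusted p = 7.33e-05), without a bound of the fold, and Csac_1628 was lower (limma adjusted p = 6.63e-05). The fold of Csac_1628 was estimated as at least 19.2. The unadjusted 95% interval of its fitted log2 difference, -6.28 to -3.24, also held smaller folds than that bound. Normalization by print block gave 15 probes, 10 higher and 5 lower, and all 7 were among them. With median centring 1 was higher and 1 lower.

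Between the mixture and xylose, 1 of 2793 probes differed. Csac_0792, above the empty spots in 1 of 2 xylose channels, rose on the mixture by a log2 difference of 3.60 ± 0.67 (SE, 4 arrays, limma adjusted p = 0.00364), and its value without the array of these 2 substrates was 2.08. It lies in a stretch of 4 consecutively numbered loci at least 2-fold higher on the mixture, of which 1 passed the test. No probe fell by limma's test, and 15 probes in either direction had an unadjusted p under 0.05. Unchanged probes alone would pass that limit at a share of 0.05, far more than 15 of 2793. The 37 probes for xylose and 29 for the mixture against glucose are under that share too. So are the 113 for xylose and 86 for the mixture against rhamnose, while the 140 for glucose against rhamnose are about at it. Between the mixture and xylose the median SE was 0.66 against an SD of 0.37 over the fitted values, so the test was strict and low counts say little about likeness. The lowest values with the same sign on both paths around the loop were -1.98 ± 0.66 for Csac_0240 and -1.81 ± 0.66 for Csac_2416, neither past the threshold (limma adjusted p = 1.00 for both). Normalization by print block gave 2 probes, both higher. Differences below that of Csac_0792 did not pass with these arrays, and a count of 1 does not show that the other probes were alike.

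**Figure D2:**
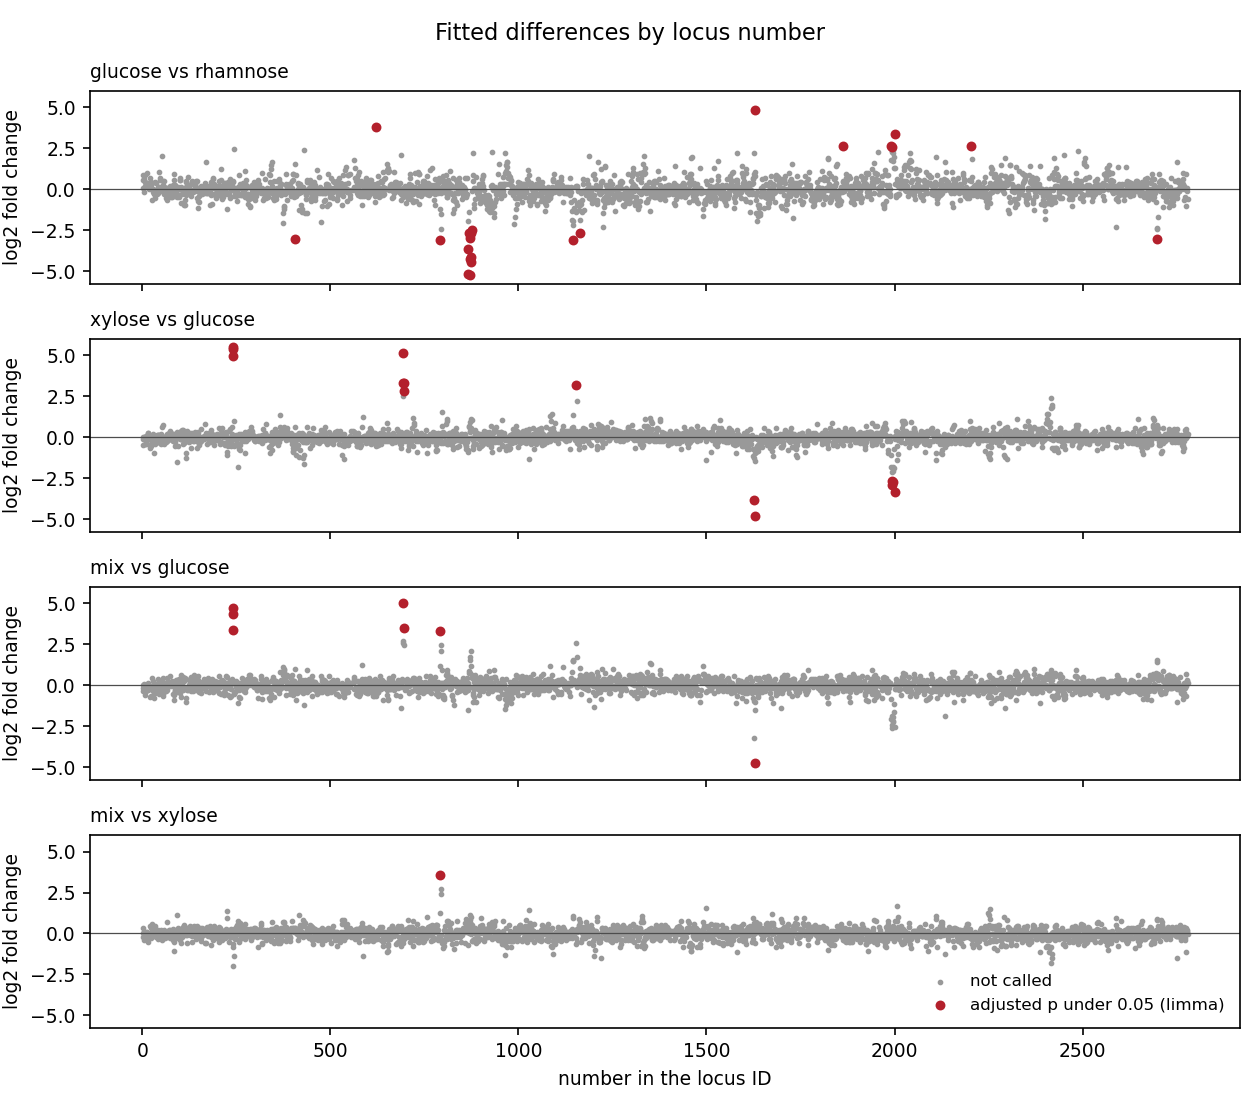
Fitted log2 difference (y axis) of each numbered locus against the number in its ID (x axis) for 4 of the 6 comparisons; grey points are probes not called and red points those with an adjusted p under 0.05 by limma. In the drawn comparisons 1 probe was called between the mixture and xylose against 24 between glucose and rhamnose, 2 of which have contig names and are not drawn.

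The 6 counts moved widely with the processing. No probe passed in any comparison by limma when the signal of the empty spots was subtracted, with 94, 79, 67, 27, 19 and 9 probes at an unadjusted p under 0.05 in the order of the comparisons above.

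The ratios were set against each other around the loop. Across probes, which are not independent replicates, the ratios of the array of the mixture and rhamnose were correlated with minus the sum of the other 3. This gave r = -0.08 (Spearman's rho -0.23). Without dye effects, arrays that share a common difference would lie above 0. A dye effect of a probe that the arrays share enters the 2 sides with opposite sign and pulls r down, whatever the substrates. With print-block normalization r was 0.40 and rho 0.19. The SD over probes of the sum around the loop was 1.54 with 1 curve per array and 0.80 with print-block normalization. This array is the one whose channel 2 is named differently by 2 labels, as rhamnose in the title and as the mixture in the channel's source. The title was used. If the array held the mixture in both channels, no probe passed in any comparison by limma, with 316, 273, 321, 86, 132 and 94 probes at an unadjusted p under 0.05.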

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

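All tests of explanations in this part were chosen after the results were seen, apart from the correlation around the loop, which was planned.

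Empty spots carried signal above their local background in all 8 channels. The median net signal of the empty spots over the median local background was 4.48 for Cy3 rhamnose, 1.90 for Cy3 glucose, 3.64 for Cy3 xylose and 1.91 for the Cy3 mixture. For Cy5 it was 1.52 for glucose, 3.41 for xylose, 2.26 for the mixture and 3.05 for rhamnose. Of 114 probes outside the authors' deposited table, 86 were above the empty spots in both channels of at least 1 substrate, and 2 of them were called, both lower on glucose against rhamnose, at -4.13 and -3.08 (limma adjusted p = 4.96e-05 and 0.00575).

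The label of channel 2 on the array of the mixture and rhamnose is in conflict, and a hybridisation of the mixture with itself was set against one with rhamnose. The planned correlation of -0.08 did not separate them, and with print-block normalization it was 0.40 (rho 0.19), the direction that rhamnose predicts. Levels were also compared. Channel 2 was above the empty spots here for 41 of 309 probes above them elsewhere on rhamnose only. For probes above elsewhere on the mixture only it was 37 of 136 (Fisher's exact two-sided p = 0.000640). It was above alone for 5 and 3 (Fisher's exact two-sided p = 0.705), and the median ratios were -0.03 and 0.14. The first set was picked by Cy3 and the second by Cy5, so a dye bias of probes gives the same. Channel 1, whose label as the mixture is not in conflict, was above for 224 of the 309 and 95 of the 136. It did not separate the sets either, so the levels cannot decide. Among probes at least 8-fold apart over the other 3 arrays, this array had 17 at least 2-fold in the opposite direction, as rhamnose predicts, and 7 in the same direction (exact two-sided binomial p = 0.0639), but 20 and 0 with print-block normalization, turned to only after that result (p = 1.91e-06, exact). Of the 39 probes at least 4-fold on this array, the other 3 gave an opposite difference of at least 2-fold at 24 and the same direction at 3 (exact two-sided binomial p = 4.92e-05), and 24 and 0 of 33 with print-block normalization (exact p = 1.19e-07). These last counts argue against a self-hybridisation under both normalizations, and the levels cannot decide. Loci changing together are not independent, so the label is not settled.

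The mean of the 4 ratios of a probe differed between print blocks, which held 67.4% of its variance against 1.68% by chance. Differences between substrates cancel in this mean by design, so no biological explanation was tested. A dye bias that depends on the place on the slide predicts that empty spots follow the probes of their block. The first test of this, over the 16 blocks with at least 5 empty spots, went against it (r = -0.05, permutation p = 0.846, rho 0.02, and r = 0.41 without the 2 farthest blocks), as did the net signal over those blocks (r = -0.28, permutation p = 0.289). Those blocks vary little in the probes (SD 0.12 against 0.31 over all), and over all 48 blocks, added after that result and with as few as 4 empty spots in a block, r was 0.716 for normalized spots (rho 0.61, and 0.721 without the 2 farthest blocks) and 0.842 for the net signal (rho 0.637, 0.832 without the 2 farthest), each with adjusted permutation p = 2e-05 over the 4 versions run, so a dye bias of this kind may account for the pattern, though neighbouring blocks are not independent and the p-values are too small for that reason.

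Consecutively numbered loci moved together. On glucose against rhamnose, 83 of 2620 neighbouring pairs were at least 2-fold in the same direction, against a mean of 11.5 when IDs were shuffled (permutation p = 1e-04, the smallest that 10000 shuffles give), and 4 pairs against 0.344 did so between the mixture and xylose. A shared print block was tested by shuffling within blocks under print-block normalization: the pairs were at least 6.56 times the shuffled mean in each of the 6 comparisons, and 2.40% of neighbours share a block, which argues against it. With that normalization 65 of the pairs on glucose against rhamnose lay in different blocks, consistent with neighbouring loci sharing a response to the substrate, such as transcription as a unit, a hypothesis found and tested on the same data. Cross-hybridisation between similar neighbours was not tested.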

How the results depend on the processing

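Counts are given in the order glucose, xylose and mixture against rhamnose, xylose and mixture against glucose, and mixture against xylose, where the reported ones were 24, 18, 14, 14, 7 and 1. Without background correction they were 38, 15, 10, 8, 5 and 0 (26 at an unadjusted p under 0.05 in the last), and with a normexp offset of 0 they were 18, 19, 21, 10, 9 and 1. Median centring gave 7, 6, 8, 6, 2 and 0 (5 unadjusted in the last) and print-block loess 77, 43, 27, 23, 15 and 2. The median over spots gave 37, 24, 17, 15, 8 and 1. Leaving out dim probes, which kept 2302, gave 8, 5, 5, 2, 1 and 0 (10 unadjusted in the last). An intensity trend and robust prior kept each count within 1.5 times. With the array of the mixture and rhamnose as a self-hybridisation all 6 limma counts were 0, with 316, 273, 321, 86, 132 and 94 at an unadjusted p under 0.05. The separate-channel fit with a dye term gave 3, 0, 0, 2, 0 and 1, with 225, 271, 165, 77, 76 and 43 unadjusted. Keeping replicate spots, whose p-values cover the spread within arrays only, gave 1326, 1219, 1068, 696, 677 and 774.

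Of the alternatives chosen after seeing the data, subtracting the empty spots gave 0 in all 6 comparisons by limma, with 94, 79, 67, 27, 19 and 9 unadjusted. Subtracting local background gave 47, 29, 18, 15, 8 and 1, and with median centring 9, 6, 7, 5, 1 and 0 (6 unadjusted in the last). The separate-channel fit without a dye term gave 5, 8, 8, 9, 8 and 0 (39 unadjusted in the last). Leaving out each array in turn, in the separate-channel fit with the dye term, gave 0 to 0 in all 6 comparisons by limma, with 126 to 423, 160 to 362, 96 to 259, 33 to 163, 144 to 347 and 24 to 157 unadjusted; that fit called few probes with all 4 arrays, so this says little about any single array. The cause of these shifts was not tested. The dim filter tests fewer probes and left the log2 values of the named calls it kept unchanged. Its prior degrees of freedom were 17.8 against 57.9 in the reported fit.

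The correlation around the loop was -0.08 as reported, -0.35 with median centring, -0.12 without dim probes, and it reversed to 0.40 with print-block loess. That loess also lowered the SD of the sum around the loop from 1.54 to 0.80. Dye effects shared by the arrays pull this correlation down, so their removal by print block may account for the reversal, which was not tested separately. None of the 22 named values changed sign under an alternative that gave it a value. With an array left out or with the self-hybridisation, no change was possible. Those values are single paths around the loop, and the naming rule required the same sign on both paths. Leaving out dim probes gave no value for 8 of the 22. Of the 20 that passed, all 20 also passed with print-block loess, 20 were lost with the empty spots subtracted, 20 with the self-hybridisation, 16 in the separate-channel fit with the dye term, 4 with local background subtracted and median centring, 3 with median centring, 5 in that fit without the dye term and 2 without background correction. Leaving out dim probes removed 8 of the 20 and ended the call of 1 of the other 12. The lost calls were not smaller folds throughout: the 20 values were 1.11 to 1.57 times the reported ones with the empty spots subtracted (median 1.32), where the median SE on glucose against rhamnose went from 0.66 to 0.85 and the prior degrees of freedom from 57.9 to 6.42, and 0.285 to 1.30 times with the self-hybridisation (median 1.03), where the SE was 0.36 and the prior degrees of freedom 2.75. The 2 that did not pass did so with replicate spots kept. Without single arrays the loop is open, so the ranges that follow also hold dye effects that cancel over all 4 arrays. Csac_0866 ranged from -3.88 to -9.06 on glucose, -3.48 to -8.66 on xylose and -1.55 to -6.73 on the mixture against rhamnose. Against rhamnose, Csac_0872 ranged from -3.05 to -5.94 on glucose and -3.44 to -6.33 on xylose, and Csac_0865 from -2.21 to -6.11 on the mixture. Csac_1627 ranged from -0.79 to -4.87 and Csac_0242 from 4.40 to 5.85 (reported 5.48, and 4.68 in the authors' table) on xylose against glucose. Csac_0242 ranged from 4.44 to 5.89 on the mixture against rhamnose (reported 4.80) and Csac_0792 from 2.08 to 4.10 on the mixture against xylose (reported 3.60). The planned counts from the authors' table were not run as tests, since its fitted values leave no residual, and the planned tests of gene lists were not run. No paired analysis was possible because each pair of substrates has 1 array. Signal over the empty spots, lowest at 1.27 for Cy5 rhamnose, limits dim probes.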

Other observations

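The position of the mixture between its 2 sugars was looked at after the counts were seen, and all tests were chosen then. At the 8 loci called higher on xylose than on glucose, the summed difference of the mixture from glucose was 0.855 of that of xylose, and at the 6 loci called higher on glucose it was 0.877. With print-block normalization these were 0.787 over 13 loci and 0.899 over 10. All 8 and all 6 lay nearer to xylose, as did 11 of the 13 and all 10 with print-block normalization, where 1 locus stood at 0.18 from glucose. None of the 8 and 6 was called between the mixture and xylose by limma, which called 1 probe there. That test was strict, with 15 at an unadjusted p under 0.05. The unadjusted 95% interval of that difference excluded 0 at Csac_0240, 1 of the 8 (-3.30 to -0.66). In 1000 simulated loops with the fitted spread and the mixture at the xylose level, 95% of positions lay from 0.892 to 1.12 for the 8 loci. For the 6 they lay from 0.843 to 1.16. The position of 0.855 is outside the first range and 0.877 inside the second. The simulations took the fitted differences as true and did not pick the loci anew. They leave out the inflation from that choice, which lowers the position, so the ranges cannot decide whether the mixture lay at the xylose level. A hypothesis is that cells on the mixture transcribe these loci nearer to their level on xylose than on glucose. A mixture at the glucose level is argued against at both sets: after adjustment 5 of the 8 and 1 of the 6 were called between the mixture and glucose, but the unadjusted 95% intervals of that difference excluded 0 at all 8, with 0.96 as the bound nearest to glucose, and at all 6, with -0.69. The intervals were turned to after those counts, and part of each difference may come from the glucose hybridisations that both comparisons share. A mixture midway between the sugars is argued against at the 8 loci, which stood at 0.730 to 0.906 with each array left out. Of these, 3 lie in the stretch of consecutively numbered loci of Csac_0240 and 4 in that of Csac_0692. Such loci move together, so the position rests on fewer independent units than 8. The limit for midway was set after the values were seen, and dye effects do not cancel with an array left out. At the 6 loci midway cannot be told apart from near xylose: they stood at 0.529 without the array of xylose and the mixture, and at 1.01 to 1.02 without each other array. Loci were picked on the difference between xylose and glucose, which inflates it, and some lie at the level of the empty spots on 1 sugar.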
